A study of Homo sapiens with 6 samples.

How the data were processed

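Poly(A) RNA of 6 THP-1 cultures, 3 from each of 2 biorepositories (ATCC and DSMZ), was sequenced after extraction with TRIzol and RNeasy columns and a stranded KAPA kit, per the labels' protocols. The labels state that cells were seeded in medium with 20% serum, grown for 48 h, split, grown for another 24 h and collected, at 37 °C and 5% CO2. Per the submitters' processing notes the tools were bcl2fastq 2.20, Trimmomatic 0.35 and kallisto 0.43.0 with the genome build GRCh38. The transcript annotation release is not given in the sources used here.

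The deposited files, 1 per library, give for each transcript its length, the effective length, the estimated count and the TPM (length-scaled abundance) as kallisto writes them, per the file headers. The estimated counts as deposited are not normalized and need not be whole numbers. The TPM values as deposited add up to the same total in each library. The files list 179973 transcripts. Of these, 163714 (91.0%) were matched to genes of GENCODE 29 on the primary assembly, 14384 by gene symbol (2.42 to 2.85% of the counts, mostly copies on alternative sequences), and 1875 had no gene (0.18 to 0.198% of the counts) and were left out. Gene coordinates are those of GRCh38.

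Estimated counts were summed over the transcripts of each of 34938 genes and rounded to whole numbers. Library totals ranged from 23413428 to 37119721 estimated counts. A count of 0 over the 3 libraries of a source allows a level of up to 0.0362 CPM in ATCC and 0.0344 in DSMZ (3 counts), and counting intervals have 95% confidence. The 10 most abundant genes held 7.08 to 8.23% of the counts and mitochondrially encoded genes 3.93 to 5.01%. No 2 libraries were close enough to be one library deposited again: the smallest chi-square per degree of freedom between libraries of a source was 4.61.

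Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test) in R 4.3.3 with the source as the only term. The biological coefficient of variation was 15.9%. Standard errors are the absolute log2 fold change divided by the square root of F. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists, chromosomes and 10 Mb windows with at least 10 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and fry was run beside it. Transcript usage was tested with diffSpliceDGE. Distances between libraries were tested by an exact permutation over the 10 splits. Figures were drawn with matplotlib 3.10.9.

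Named genes were fixed by rule before the data were examined. They are the 10 highest and 10 lowest log2 fold changes of protein-coding genes past the threshold, without overlap of the libraries and with a mean of at least 8 CPM. They also include up to 4 members of each list, 16 fixed genes, up to 4 genes for each of 5 called chromosomes or windows, 5 genes for transcript usage and the 5 most abundant genes of each source among those detected in 1 source only. Some of the examined genes, 1 gene list and 1 test of the closing section are not reported here. Genes named with Xq28 or as families in the closing section were chosen after their values were seen. Chromosome Y was left out of the chromosome test, and its genes and XIST are not named.

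The gene test was run on simulated counts drawn from the real means and library sizes. Over 14394 genes it found 8 of 67 genes changed 1.5-fold, 44 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 10 false calls. The chromosome test found the 1 changed chromosome with 0 false calls. With no change simulated, the list and window tests made 0 false calls. Genes were drawn independently of each other and without a GC trend. These runs therefore say little about sets of correlated genes in the real libraries. Transcript usage recovered less: diffSpliceDGE found 16 of 200 genes changed 2-fold with 69 false calls, and the fraction test found 2 of 200 at 2-fold with 0 false calls and 129 of 200 at 4-fold with 13 false calls.

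Alternatives fixed before the data were examined were other normalizations, DESeq2 1.42.0, limma on log2(TPM + 0.5) and voom, other filters on low counts, a transcript length offset, protein-coding transcripts only, a GC correction, a replicate block, thinning to the smallest library and leaving out each library in turn. Added after seeing the data were primary assembly transcripts only, centring on 10 Mb windows, lists without the called chromosomes, the fraction test, and the GC correction for lists, chromosomes and windows. GC content was available for 99.9% of tested genes.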

Results

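THP-1 is a human acute monocytic leukaemia cell line that grows in suspension and is distributed by several cell banks. RNA was sequenced from THP-1 cells obtained from the American Type Culture Collection (ATCC) and from the German collection DSMZ, with 3 libraries from each bank. Cells of both banks were grown at the same time in RPMI with 20% fetal bovine serum and were collected untreated during logarithmic growth. The labels state that the replicate expansions were made independently. P-values therefore rest on the spread between replicate expansions of a bank. A difference between the banks cannot be told apart from one between the particular cells obtained from each. In order of replicate number, the ATCC libraries held 28198941, 25632895 and 27811159 estimated counts and the DSMZ libraries 23413428, 28515838 and 37119721. Every fold change is DSMZ minus ATCC on the log2 scale, so that positive values are higher in DSMZ. Levels are in CPM, library-scaled counts, as mean ± SD over n = 3 libraries.

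The first question was whether the banks' cells differ by more than the replicate cultures of each bank. The first principal component held 82.0% of the variance and separated the sources, with the ATCC libraries between -68.4 and -60.0 and the DSMZ libraries between 63.0 and 64.7. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM between DSMZ libraries was 0.992 to 0.994, between ATCC libraries 0.975 to 0.992 and between libraries of different sources 0.911 to 0.925. The mean distance between libraries of different sources was 2.70 times that between libraries of the same source, against 0.875 to 0.948 times in the other splits. The exact one-sided permutation p for a ratio this large was 0.1, the smallest that 10 splits of 3 against 3 libraries can give. ATCC replicate 2 stood apart from the other ATCC libraries: it lay at -43.5 on the second component (10.3% of the variance), where ATCC replicates 1 and 3 lay at 31.4 and 14.7. Its low-GC transcripts were low, with a median deviation from the other ATCC libraries of -0.92 in the lowest of 10 groups of genes by GC content and 0.34 in the highest.

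**Figure D1:**
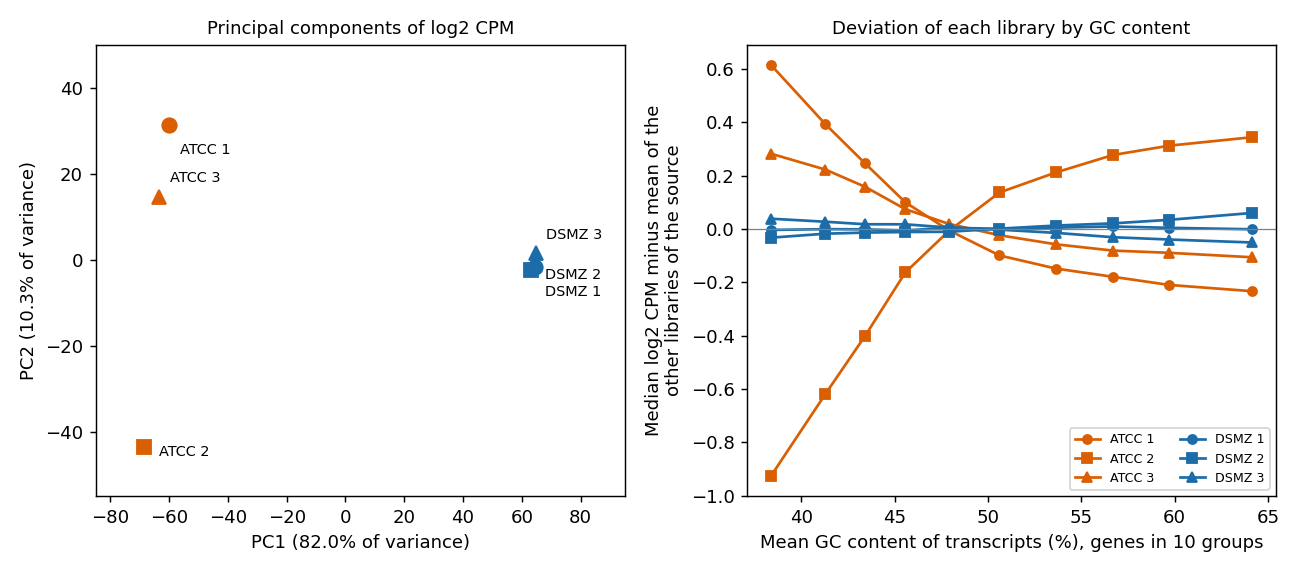
Left, principal components of log2 CPM for each of the 6 libraries (orange, ATCC; blue, DSMZ; circle, square and triangle, replicates 1, 2 and 3), with the sources on opposite sides of the first component and ATCC replicate 2 at -43.5 on the second. Right, the median deviation of each library from the mean of the other libraries of its source, for genes in 10 groups of increasing GC content: ATCC replicate 2 runs from -0.92 to 0.34, while ATCC replicates 1 and 3, whose references include replicate 2, run from 0.61 to -0.23 and from 0.28 to -0.11.

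As first fitted, about as many genes passed the test of a difference between the sources as did not. The share depends on the setting: with the GC correction 9294 of the 14580 tested genes passed, and 98.6% of the calls as first fitted were kept. Among the genes highest in DSMZ was LIN28B (chromosome 6, 104936616 to 105083332), an RNA-binding protein that blocks maturation of let-7 microRNAs, at 97.9 ± 6.14 CPM against 0.0600 ± 0.0407 in ATCC. Emerin (EMD, chromosome X, 154379197 to 154381523), a protein of the inner nuclear membrane, had 0 counts in the 3 ATCC libraries and 23.6 ± 1.60 CPM in DSMZ, at least 652.6-fold higher against a floor of 3 counts over the group. In ATCC, DMRTA2 (chromosome 1, 50417550 to 50423500), a DM-domain transcription factor, reached 105 ± 11.1 CPM against 0.191 ± 0.118 in DSMZ. N-cadherin (CDH2, chromosome 18, 27950966 to 28177446) reached 23.6 ± 2.37 against 0.0473 ± 0.0218. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7261 of 14580 tested genes passed an adjusted p of 0.05, of which 3513 were higher in DSMZ and 3748 in ATCC. At least 2-fold differences were found in 3112 genes, 1445 higher in DSMZ and 1667 in ATCC. With upper quartile normalization, which shifted the median fold change of all genes to -0.07, 42.4% of calls were higher in DSMZ, against 48.4% as first fitted. The 3 libraries of each source did not overlap in 9094 genes (62.4%), where chance gives 10%.

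The other genes with the largest differences at a mean of at least 8 CPM are given by direction. Higher in DSMZ were PPP1R3A, a glycogen-targeting subunit of protein phosphatase 1 (log2 fold change 9.49, SE 0.27), MEIS1, a homeobox partner of HOXA9 in leukaemia (7.75, SE 0.23), the matrix protein SPARC (7.65, SE 0.16), HORMAD1, a meiotic chromosome protein (7.53, SE 0.23), dysferlin (DYSF; 7.18, SE 0.37), the zinc finger gene ZNF595 (6.75, SE 0.37) and the RNA-binding protein IGF2BP1 (6.68, SE 0.19). The GTPase RAB34 had 3 counts in ATCC and 43.9 ± 2.41 CPM in DSMZ, a ratio of 1212 with a 95% counting interval of 414 to 5879. Higher in ATCC were the orphan receptor GPR27 (-8.44, SE 0.29), BEND4 (-8.19, SE 0.40), the axon guidance receptor ROBO1 (-8.09, SE 0.29), the neuronal transcription factor POU4F2 (-7.57, SE 0.16), the adaptor APBA1 (-6.85, SE 0.25), the protocadherin PCDHB2 (-6.33, SE 0.19) and the receptor phosphatase PTPRG (-6.24, SE 0.29). The protease ADAMTS15 had 18.0 ± 2.48 CPM in ATCC and 2 counts in DSMZ, a ratio of 783 (216 to 6468). Intervals and floors cover counting error only. The adjusted p of these genes in edgeR's quasi-likelihood test lay between 8.84e-07 and 1.8e-05.

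The fixed gene lists asked which cell programmes differ between the stocks. Genes of glycolysis and the hypoxia response were higher in DSMZ: 19 of 28 tested members were higher there and 1 was lower (20 and 1 adjusted over the list alone), with a median log2 fold change of 1.13. They included the glycolytic enzymes ALDOC (49.6 ± 10.4 CPM in DSMZ against 3.89 ± 1.66; log2 fold change 3.68, SE 0.32) and ENO2 (3.56, SE 0.14), the mitophagy receptor BNIP3 (2.60, SE 0.16) and PFKFB4, a regulator of glycolytic flux (2.54, SE 0.23). This was the only one of 36 tested lists that camera called on the edgeR fit (adjusted p = 1.11e-09). The call was lost with an estimated correlation (camera adjusted p = 0.825 with an estimated correlation). It was also lost on the 10 members outside the chromosomes that differed as a whole (camera adjusted p = 0.0941, with a median of 0.58). Mixed splits of the libraries called up to 10 lists. They keep part of the source difference, so this is not a count of false calls. Centring the genes on 10 Mb windows, a setting chosen after seeing the data, kept the call (adjusted p = 6.15e-06). It lowered the median of the 18 members on called chromosomes from 1.57 to 0.57, beside 0.58 and 0.65 for the other 10.

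No other list passed the camera test as first fitted, and the counts that follow are of single members past edgeR's adjusted p. The lists of MHC class II and of chromatin regulators passed in some other settings, given in the closing section. Member values were not corrected for the shift of their chromosome, given below, so they need not reflect a cell programme. Values of members without a unit are log2 fold changes. MHC class II antigen presentation had 10 of 17 tested members higher in DSMZ and 3 higher in ATCC (adjusted p = 0.0594), led by HLA-DRA (164 ± 40.8 CPM in DSMZ against 6.08 ± 2.67; 4.76, SE 0.36), HLA-DPA1 (4.03, SE 0.26), HLA-DPB1 (3.59, SE 0.29) and the peptide exchange subunit HLA-DMB (1.87, SE 0.51). MHC class I antigen presentation had 9 of 22 higher in DSMZ and 4 in ATCC, with HLA-F at 1.21, the peptide-trimming ERAP1 at 0.94, TAPBPL at 0.87 and the transcription factor IRF1 at 0.84. Type I interferon response genes went both ways, with 10 of 33 higher in DSMZ, such as IFIT3 (2.10), and 8 higher in ATCC, such as IFITM3 (-2.28), RSAD2 (-2.25) and OAS3 (-2.17). Of 20 NF-kappaB and inflammatory cytokine genes, 6 were higher in DSMZ, among them the chemokine CCL20 (3.86), ICAM1 (2.27) and CD83 (1.53), and 3 in ATCC, among them CXCL1 (-2.59). Pattern recognition and inflammasome genes had 9 of 26 higher in ATCC and 0 in DSMZ, including the flagellin receptor TLR5 (-2.65), the lipopolysaccharide co-receptor CD14 (-2.01), pyrin (MEFV, -1.46) and NLRP1 (-1.30). Checkpoint ligands and costimulation genes had 6 of 23 higher in each source, with MICB (1.42) higher in DSMZ and SIGLEC9 (-2.31), TNFRSF14 (-2.13) and SIGLEC7 (-1.97) in ATCC. SIGLEC9 was scarce, at 0.423 ± 0.0331 CPM in ATCC and 0.0932 ± 0.0874 in DSMZ (7 counts; SE 0.65).

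Markers of monocytes and macrophages also went both ways. Of 26 tested monocyte markers 5 were higher in DSMZ and 12 in ATCC (6 and 12 adjusted over the list alone). The proteoglycan VCAN was at 145 ± 28.3 CPM in ATCC and 6.91 ± 0.487 in DSMZ (-4.39, SE 0.18), while the alarmins S100A8 (2.38, SE 0.19) and S100A9 (1.77, SE 0.19) were higher in DSMZ. Macrophage markers had 5 of 17 higher in DSMZ and 8 in ATCC (5 and 9 adjusted over the list alone). Lipoprotein lipase (LPL) was at 144 ± 22.3 CPM in ATCC and 14.8 ± 0.563 in DSMZ. The apolipoprotein APOE (2.26) and ADGRE1 (2.28) were higher in DSMZ. VSIG4 had 3 counts in DSMZ, where the ratio of ATCC to DSMZ was 26.0 (8.56 to 129). Granulocyte and azurophil granule genes had 5 of 16 higher in each source. Those with the largest fold changes were higher in DSMZ: myeloperoxidase (MPO) reached 90.4 ± 17.7 CPM there against 10.9 ± 0.995, beside BPI (3.01), DEFA4 (1.63) and CEBPE (1.42). Summed over the list, the level was higher in ATCC, at 5741 ± 431 CPM against 4686 ± 194 in DSMZ. Dendritic cell markers had 1 of 8 higher in DSMZ, CCR7, with 2 counts in ATCC and a ratio of 21.3 (5.57 to 182). The 4 higher in ATCC included CD209 (-3.26), BATF3 (-1.42) and the transcription factor IRF8 (757 ± 87.2 CPM against 349 ± 31.0; -1.12). Phagocyte oxidase and phagocytic receptor genes had 4 of 20 higher in DSMZ, with NCF1 at 2.86, CR1 at 2.06 and CYBB at 1.55, and 7 higher in ATCC. NCF1 has near-identical pseudogenes, so its value is uncertain.

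Of the regulators of blood cell identity, the stem cell and KMT2A fusion target genes had 8 of 24 members higher in DSMZ, led by MEIS1 (7.75) and ARID2 (1.87) with JMJD1C (1.23), and 7 higher in ATCC, led by RUNX2 (106 ± 7.65 CPM against 19.1 ± 2.93; -2.47). Myeloid transcription factors had 7 of 23 higher in each source, with ERG (-2.47) and KLF4 (-1.67) higher in ATCC and EGR2 (1.92) in DSMZ. MAF had 1 count in DSMZ and a ratio of ATCC to DSMZ of 88.6 (15.5 to 3540). Chemokine and cytokine receptors had 7 of 29 higher in DSMZ, such as CXCR4 (1.91), and 13 in ATCC, such as IL21R (-2.72) and IL1R1 (-2.36). Integrins and adhesion molecules had 5 of 24 higher in DSMZ and 9 in ATCC, where the collagen receptor subunit ITGA2 (-5.26), ITGAL (274 ± 66.1 CPM against 40.9 ± 6.35; -2.75) and ITGB5 (-2.09) were higher. Immediate early genes had 6 of 24 higher in each source, with KLF2 at 3.10, DUSP4 at -1.94 and FOS at -1.74.

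Lists of proliferation, repair and stress genes were examined in the same way. Cell cycle genes had 15 of 35 higher in DSMZ and 7 in ATCC, including the proliferation antigen MKI67 (1.26), the replication clamp PCNA (1.26), CDK1 (1.07) and CDC20 (-1.08). Apoptosis regulators had 7 of 26 higher in DSMZ and 6 in ATCC (8 and 6 adjusted over the list alone), among them BCL2A1 (2.93), BMF (1.21) and CASP10 (0.96). DNA repair genes had 5 of 28 higher in DSMZ and 3 in ATCC (3 and 3 adjusted over the list alone), with BRCA2 at 1.75, FANCD2 at 0.86 and ERCC2 at -0.65. DNA methylation and chromatin regulators had 15 of 28 higher in DSMZ and 3 in ATCC (16 and 3 adjusted over the list alone; camera adjusted p = 0.0594), with the demethylating enzyme TET1 at 2.46, the histone methyltransferase KMT2D at 1.77, KDM5A at 1.63 and HDAC9 at -2.96. ATF4 and amino acid response genes had 3 of 25 higher in DSMZ and 11 in ATCC (3 and 12 adjusted over the list alone), with ATF5 at -2.31, NUPR1 at -1.87, STC2 at 2.50 and DDIT4 at 1.77. Unfolded protein response and heat shock genes had 5 of 23 higher in each source (4 and 5 adjusted over the list alone), with HSPA1A at 0.85, EDEM1 at 0.71, HSPA8 at -0.72 and HSPB1 at -0.71. Replication-dependent histones had 10 of 16 higher in DSMZ and 0 in ATCC, such as HIST1H3H (2.19), HIST1H2AC (1.59), HIST1H4H (1.26) and HIST1H2BD (1.08), at up to 3.55 CPM in these poly(A)-selected libraries.

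Among metabolic lists, cholesterol biosynthesis and uptake had 4 of 24 members higher in DSMZ and 10 in ATCC (4 and 11 adjusted over the list alone), with SQLE at -1.60, NSDHL at -1.30, IDI1 at 1.27 and INSIG1 at 1.26. Lipid efflux and LXR target genes had 6 of 15 higher in each source. The desaturase SCD reached 742 ± 126 CPM in DSMZ against 144 ± 6.05 (2.36). SREBF1 was at 1.91, CD36 at -1.73 and the cholesterol exporter ABCA1 at -1.24. Nuclear-encoded oxidative phosphorylation genes had 10 of 38 higher in DSMZ and 13 in ATCC, with NDUFA9 at 1.20, NDUFS1 at 0.95, CYC1 at -1.11 and NDUFA8 at -1.02. Mitochondrially encoded genes had 4 of 12 higher in DSMZ and 0 in ATCC, namely MT-ND6 (1.34), MT-CO3 (0.79), MT-ATP6 (0.64) and MT-CYB (0.61). Ribosomal protein genes had 12 of 49 higher in DSMZ and 14 in ATCC, with RPS24 at 0.97, RPL18 at -1.07, RPL8 at -1.05 and RPL7 at -0.92. Many have processed pseudogenes that can take reads.

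Markers of other cell types were examined as well. B cell markers had 5 of 8 higher in DSMZ and 2 in ATCC. CD79B was at 9.47 ± 1.49 CPM in DSMZ against 0.972 ± 0.286 (3.28), POU2AF1 at 2.16 and CD79A at 2.13. IGLL1 had 2 counts in ATCC and a ratio of 27.5 (7.28 to 232). Summed over the B cell list, levels were alike, at 31.2 ± 8.11 CPM in ATCC and 32.9 ± 2.44 in DSMZ. T and NK cell markers had 1 of 4 higher in DSMZ, CD8A (2.14), and 2 in ATCC, CD5 (-3.60) and NKG7 (-1.44). Megakaryocyte markers had 0 of 4 higher in DSMZ and 2 in ATCC, TREML1 (-2.25) and VWF (-0.84). The whole megakaryocyte list summed to 5.52 ± 1.16 CPM in ATCC and 3.05 ± 0.694 in DSMZ. Epithelial markers had 0 of 5 higher in DSMZ and 2 in ATCC, ESRP1 (-1.76) and CLDN7 (-1.13). Fibroblast markers had 3 of 9 higher in each source (3 and 4 adjusted over the list alone), with COL6A1 at 21.4 ± 0.310 CPM in ATCC against 2.11 ± 0.150 (-3.33), PDGFRA at -3.44, FBN1 at 1.37 and PDGFRB at 1.00. Cancer-testis antigens had 2 of 5 higher in DSMZ and 3 in ATCC, with SYCP1 at 2.49, MAGEA4 at -1.17, XAGE1B at -1.12 and PRAME at -0.96. The erythroid list was not tested because it had 2 measured members, EPOR (0.51) and KLF1, with 3 counts in ATCC and a ratio of 14.9 (4.78 to 74.6). Where no second pair of counts is given, the counts adjusted over the list alone were equal to those over all genes. The median and the direction of the camera test had opposite signs for the interferon, granulocyte, lipid efflux, oxidative phosphorylation, checkpoint and epithelial lists, and the mean of the phagocyte list (0.05) went against its median (-0.26).

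**Figure D2:**
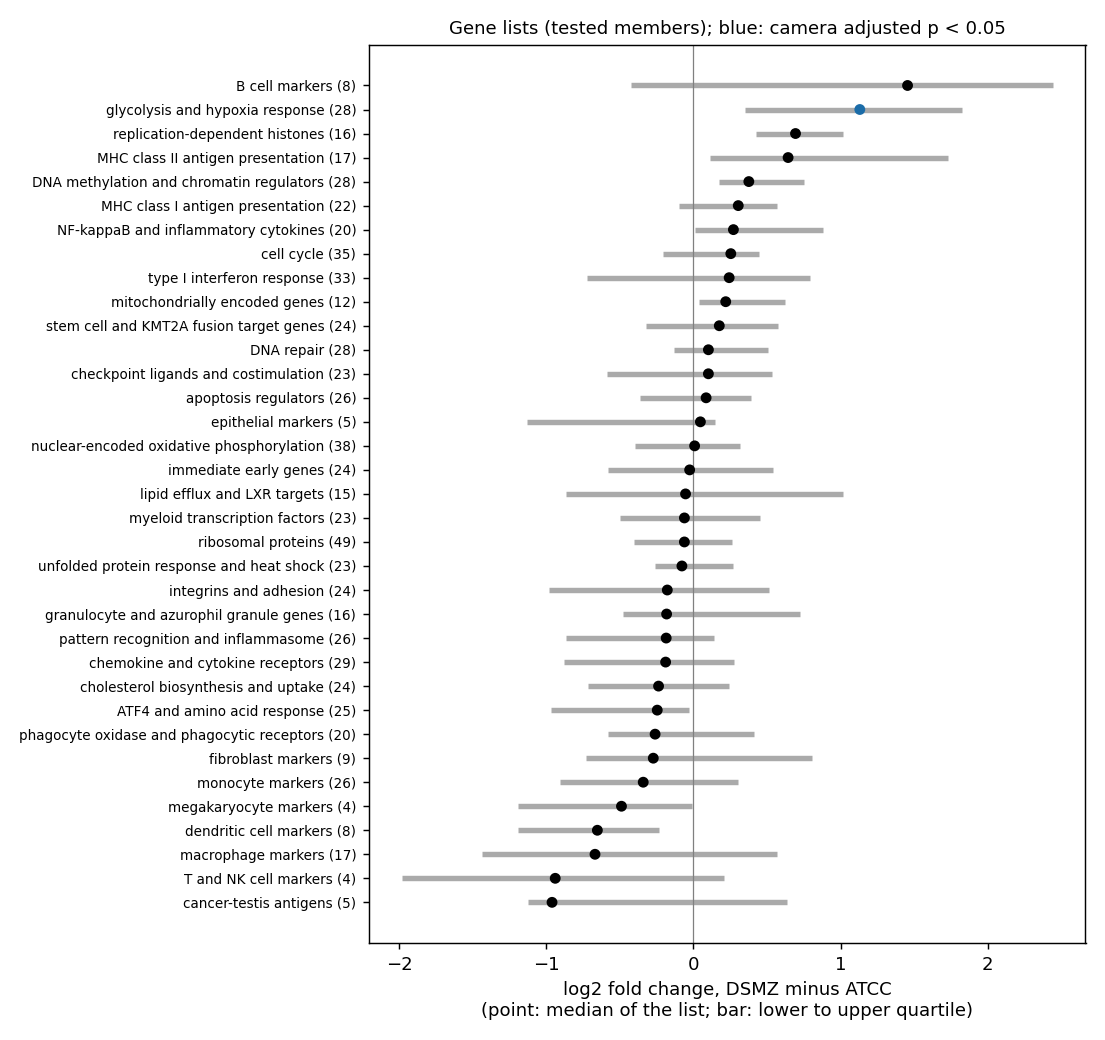
Median log2 fold change (DSMZ minus ATCC) of 35 of the 36 tested lists, with the number of tested members in brackets and a bar from the lower to the upper quartile of the members. The list passing camera's adjusted p is blue: glycolysis and hypoxia response, with a median of 1.13 (adjusted p = 0.825 with an estimated correlation).

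A fixed set of 16 genes of the line's known lesions and surface identity was examined whatever the values. This paragraph gives 11 of them, and CD14 is given above. MLLT3, the fusion partner of KMT2A in this line, was at 15.7 ± 1.86 CPM in DSMZ and 10.1 ± 2.39 in ATCC (0.63, SE 0.19). CDKN2A and CDKN2B, neighbouring cell cycle inhibitor genes on chromosome 9, had 0 counts in all 6 libraries, which allows up to 0.0362 CPM in ATCC and 0.0344 in DSMZ. HLA-C (0.53, SE 0.12), B2M (0.30, SE 0.09) and the receptor CSF1R (0.60, SE 0.18) were higher in DSMZ. The myeloid transcription factor SPI1 was lower (-0.41, SE 0.13). KMT2A (0.19, SE 0.18; edgeR adjusted p = 0.406), HLA-B (0.34; 0.0791), MTAP (0.33; 0.293) and NRAS (0.39; 0.115) did not pass. HLA reads can be shared among family members and haplotype copies, which makes these values uncertain.

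Because sublines of a leukaemia can differ in their chromosomes, the tested genes of each chromosome were compared as sets. Genes of chromosome 10 were higher in DSMZ with a median log2 fold change of 1.03: 406 of 534 were higher there and 25 higher in ATCC (415 and 25 adjusted over the list alone). Genes of chromosome 8 (median -0.86) and of chromosome X (median -0.82) were higher in ATCC. On chromosome 8, 327 of 469 genes were higher in ATCC and 19 in DSMZ (338 and 20 adjusted over the list alone), and on chromosome X 339 of 492 and 27 (350 and 28 adjusted over the list alone). On chromosome 10 these included OGDHL, a 2-oxoglutarate dehydrogenase relative (17.2 ± 0.945 CPM against 0.739 ± 0.0989; 4.54, SE 0.15), the proteoglycan SRGN (3578 ± 234 against 1005 ± 14.7; 1.83, SE 0.08), FUT11 (2.13) and the homeobox gene HHEX (2.00). On chromosome 8, carbonic anhydrase CA2 was at 1687 ± 193 CPM in ATCC and 62.2 ± 10.9 in DSMZ (-4.76, SE 0.17), beside ADGRA2 (-4.13), TSPYL5 (-3.69) and the Wnt antagonist SFRP1 (-3.10). On chromosome X, the chloride transporter CLCN4 (-2.94) and DCAF12L1 (-4.01) were higher in ATCC, while the transketolase-like TKTL1 (3.36) and filamin A (FLNA, 4.20) were higher in DSMZ.

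Of 23 chromosomes, 11 passed camera's adjusted p on the edgeR fit. Besides 10, 8 and X these were 9 (median -0.41), 11 (-0.36), 17 (0.38), 20 (0.32), 13 (0.35), 3 (0.31), 6 (0.20) and 12 (0.20). Shifts of this size also occurred within ATCC. Against the other ATCC libraries, ATCC replicate 2 had a median of -0.37 on chromosome 13 and of -0.39 on chromosome 4, which did not pass. Without that library the source medians of chromosomes 9, 11, 17 and 20 were -0.39, -0.33, 0.43 and 0.36. Chromosome 12 was mixed along its length, with a median of 0.99 over 140 genes at 0 to 20 Mb, 0.54 over 256 genes at 40 to 70 Mb and -0.35 over 139 genes at 110 to 130 Mb. On chromosome 20 the first 20 Mb had a median of 0.88 (76 of 105 genes higher in DSMZ, 2 in ATCC), on chromosome 6 the first 40 Mb had 0.52, and on chromosome 1 the stretch from 200 to 240 Mb had -0.52. In 10 Mb windows, 103 of 294 passed. The window of chromosome 10 at 100 to 110 Mb had 56 of 61 genes higher in DSMZ and 0 in ATCC, among them DPCD (2.62), SCD (2.36), SEC31B (1.92) and the hydroxylase HIF1AN (1.40). The window of chromosome 12 at 0 to 10 Mb had 74 of 95 higher in DSMZ and 6 in ATCC, among them ENO2 (3.56), CRACR2A (2.22), CLSTN3 (2.04) and the adiponectin receptor ADIPOR2 (1.32). With an estimated correlation the calls of chromosomes 8, 9, 10, 12 and X held, the other 6 were lost (adjusted p = 0.282 to 0.856 with an estimated correlation) and 0 windows passed. With the preset correlation, splits that mixed the sources called up to 15 chromosomes and 160 windows. These splits keep part of the source difference, so their counts are not counts of false calls.

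**Figure D3:**
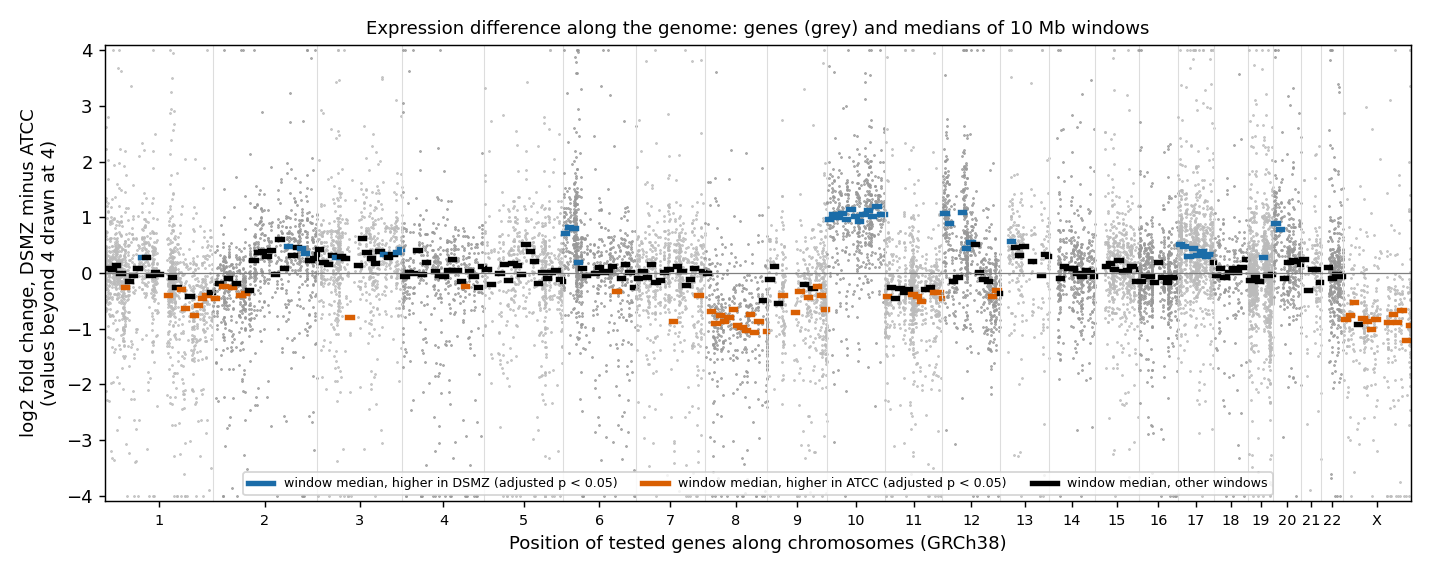
Log2 fold change (DSMZ minus ATCC) of tested genes (grey points) along the chromosomes, with the median of each 10 Mb window that holds at least 10 tested genes as a bar, blue or orange where camera's adjusted p passed. The 14 windows of chromosome 10 have medians between 0.94 and 1.21, and chromosomes 8 and X lie below 0 along most of their length.

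Genes detected in 1 source only were counted with fixed limits, at least 1 TPM in all 3 libraries of a source and at most 0.1 TPM in all 3 of the other. There were 41, of which 28 were detected in ATCC and 13 in DSMZ. The ATCC genes with the highest TPM were GPR27 (13.5 ± 0.478 TPM), CDH2 (12.2 ± 2.69), LRRC4B (4.93 ± 0.298), BEND4 (4.91 ± 1.74) and ALKAL1 (4.79 ± 1.10). LRRC4B, a synaptic adhesion protein, had 3 counts in DSMZ and a ratio of ATCC to DSMZ of 341 (116 to 1655). The DSMZ genes with the highest TPM were EMD (34.0 ± 2.56 TPM), PPP1R3A (27.1 ± 2.01), LIN28B (22.2 ± 1.07), the microfibril protein MFAP2 (8.40 ± 1.28) and PPP1R1B (3.30 ± 1.25). MFAP2 had 2 counts in ATCC and a ratio of 276 (76.2 to 2288), and PPP1R1B had 1 count and a ratio of 246 (43.7 to 9737). Of these 41 genes, 27 ATCC and 12 DSMZ genes passed the filter on counts, and all of those passed edgeR's adjusted p. The number depends on the limits, with 11 genes at 2 and 0.05 TPM and 81 at 0.5 and 0.1 TPM.

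Because the files list single transcripts, the share of each transcript in its gene was compared as well. FLNA, which encodes an actin-crosslinking protein (chromosome X, 154348524 to 154374638), was counted in different transcripts in the sources. In ATCC, 82.4% ± 2.42 of its counts lay in ENST00000490936.5, a retained-intron transcript of the gene's 3' part (154348648 to 154359638), against 1.36% ± 0.0846 in DSMZ. The full-length ENST00000369850.7 took 0% in ATCC and 49.1% ± 0.382 in DSMZ. ENST00000610817.4, a protein-coding transcript over about the same span, had 236 estimated counts over the 3 ATCC libraries and 0 in DSMZ. An estimated count does not show where along a transcript the reads lie. Whether ATCC cells make full-length FLNA was therefore not settled. NACA, a chaperone subunit at the ribosome, had 0.00733% ± 0.00637 of its counts in ENST00000548563.5 in ATCC and 4.07% ± 1.39 in DSMZ. In the tubulin gene TUBB, ENST00000422674.6 held 99.4% ± 0.0496 in ATCC and 73.0% ± 0.963 in DSMZ. In HLA-B ENST00000450871.6 held 71.3% ± 1.47 and 53.7% ± 1.03. Of 10409 genes tested, 286 passed edgeR's diffSpliceDGE, 335 passed a limma test on transcript fractions that was chosen after seeing the data, and 186 passed both. Other settings of diffSpliceDGE moved the count: 47 genes with a filter at 5 CPM, 169 with the replicate numbers as a block and 437 with its gene-level F test. The TUBB and HLA-B transcripts lie on alternative haplotype sequences, among which kallisto splits the reads of nearly identical copies. On simulated data diffSpliceDGE found 16 of 200 genes changed 2-fold with 69 false calls, so single calls are uncertain.

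**Figure D4:**
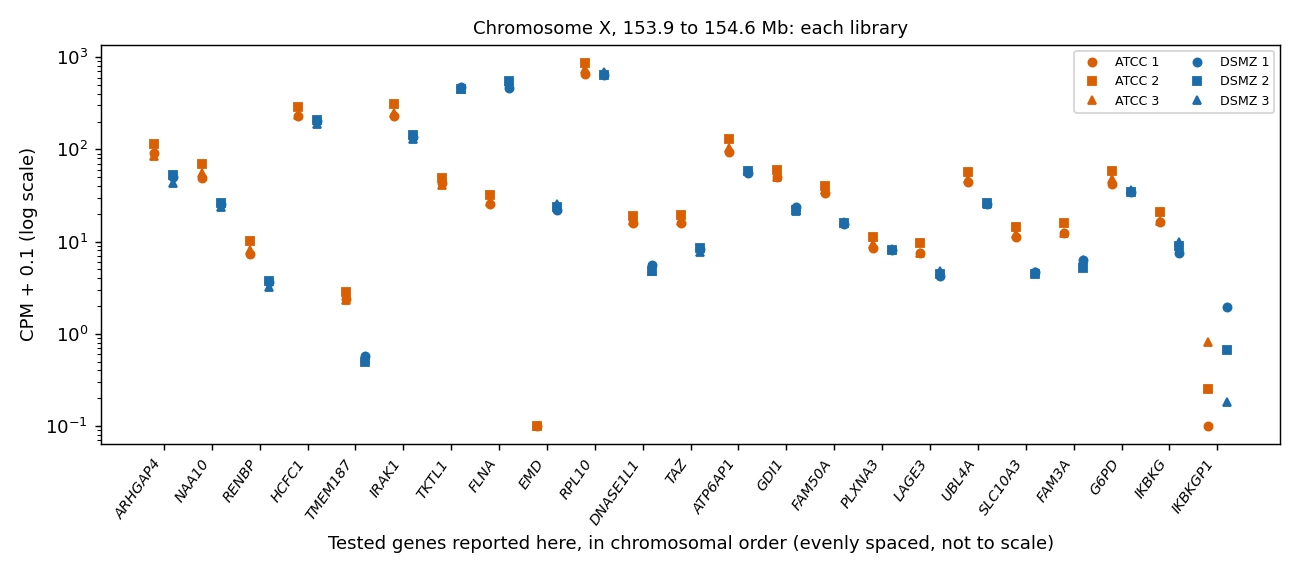
CPM + 0.1 on a log scale of each library (orange, ATCC; blue, DSMZ) for tested genes reported here of the stretch of chromosome X around FLNA, evenly spaced in chromosomal order. TKTL1, FLNA and EMD are higher in the DSMZ libraries, while most of the genes on either side are lower there.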

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

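Chosen only after the result was seen were the settings centred on 10 Mb windows, without the called chromosomes, primary assembly transcripts only, the transcript fraction test, the GC correction of lists, chromosomes and windows, and the counts over other splits. The number of genes differing stayed within 5468 (centred on windows) and 9517 (without ATCC replicate 2) of the 7261 as first fitted. With DESeq2, 6703 of the 7261 calls were shared in direction. Fewer were kept with window centring (60.6%), the filter at 5 CPM (74.6%) and without DSMZ replicate 2 (74.6%). Under window centring 94 genes were called in the opposite direction, by construction. So were 2 genes with protein-coding transcripts only and 1 with primary assembly transcripts only, though not by construction. Of 193 genes chosen to be named over all settings, 3695 values kept call and direction, 81 lost the call, 11 gained one and 0 reversed. Thinning all libraries to the total of the smallest gave 7072 genes, 3025 of them at least 2-fold. A filter at 5 CPM, which tests fewer genes, left 1849 genes differing at least 2-fold (857 higher in DSMZ, 992 in ATCC). Centring on windows left 963 higher in DSMZ and 1363 higher in ATCC at least 2-fold. Called lists numbered 0 with an estimated correlation, 2 with the GC correction (DNA methylation and chromatin regulators added), 23 with fry, which does not compare a list with other genes, 0 without the called chromosomes and 3 centred on windows. The glycolysis list had adjusted p between 1.34e-11 and 0.0941 over settings with the preset correlation. With an estimated correlation 5 chromosomes and 0 windows were called. Genes of 1 source only numbered 11 with limits of 2 and 0.05 TPM and 81 with 0.5 and 0.1 TPM. Transcript usage gave 437 genes with the gene-level F test and 47 with a 5 CPM filter. The distance ratio was 4.06 over the 500 most variable genes. The cause of these shifts was not tested unless stated.

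Leaving out each library in turn gave 5516 to 9517 genes, 3036 to 3423 at least 2-fold, 1 to 2 lists, 11 to 12 chromosomes, 102 to 123 windows, 46 to 56 genes of 1 source only, 289 to 366 genes of transcript usage and a distance ratio of 2.42 to 3.31. Without ATCC replicate 2 the chromatin list passed (adjusted p = 0.0401), and without DSMZ replicate 1 or 3 the MHC class II list did (0.0407 and 8.16e-05). Over all settings with the preset correlation these lists ranged from 0.0216 to 0.524 and from 8.16e-05 to 0.677. Same-numbered libraries had correlations of 0.0132, 0.0806 and 0.162. All libraries but DSMZ replicate 1 correlated best with their own number, and that library did so with ATCC replicate 2 (0.0254). The numbers were not taken as pairs, but a pairing is not excluded. With the replicate block 7019 genes, 2 lists (MHC class II added) and 169 genes of transcript usage were called.

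The 6 libraries allow 10 splits, too few for a share under 0.05. Real values and the highest of the other splits were 7261 and 0 genes, 3112 and 0 at least 2-fold, 1 and 10 lists, 11 and 15 chromosomes, 103 and 160 windows, and 286 and 76 genes of transcript usage. As many as in the real split were found in 1, 1, 10, 8, 10 and 1 of the 10 splits. The other splits mix the sources 2 to 1. There the tests with a preset correlation called as many lists and windows as in the real split in 9 of 9 splits, and as many chromosomes in 7. Mixed splits keep the source difference, partly in the contrast and partly in the spread within groups. Their counts, also the 0 genes, are therefore not counts of false calls.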

Other observations

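Chosen only after the result was seen were the tests of gene families and of chromosome 10 without ATCC replicate 2 and along its windows. So were the test of the share of FLNA counts in long transcripts and all tests of ATCC replicate 2. The GC correction of chromosome 10 was added after its shift was seen, but the bound for that test was written before the corrected median was seen. Protocadherin beta genes, a cluster of neuronal adhesion molecules on chromosome 5, were lower in DSMZ: 10 of 12 tested members, with a median log2 fold change of -2.09. PCDHB2 was at 21.6 ± 1.5 CPM in ATCC and 0.264 ± 0.0776 in DSMZ, PCDHB13 at 8.51 ± 2.07 and 0.497 ± 0.0552, and PCDHB16 at 5.24 ± 1.05 and 0.305 ± 0.0751 (n = 3 each). Among 183 families sharing a symbol stem, this family had a camera adjusted p of 8.78e-09 (2.15e-05 with the GC correction, 0.983 with an estimated correlation). Genes with the stem SIGLEC, mostly of the family of sialic acid receptors of leukocytes, had 11 of 13 members lower in DSMZ (median -1.83, camera adjusted p = 0.0085). The 13 include the pseudogenes SIGLEC17P and SIGLEC22P. That call was lost with the GC correction (0.107) and with an estimated correlation (0.983). SIGLEC12 was at 6.26 ± 1.31 CPM in ATCC and 0.630 ± 0.161 in DSMZ, and SIGLEC14 at 8.54 ± 0.785 and 3.24 ± 0.145. Members of both families are alike in sequence, so their single values are uncertain.

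Genes of chromosome 10 were higher in DSMZ along the whole chromosome: 477 of 534 genes (89.3%) lay above 0, the lower quartile was 0.60, and 14 of 14 windows had medians above 0, from 0.94 to 1.21. GC content as the cause is argued against by a median of 1.02 after the GC correction, against 1.03 without it, and ATCC replicate 2 as the cause by 0.98 without that library. A candidate explanation is more copies of chromosome 10 per cell in the DSMZ stock, since the shift covers 14 of 14 windows, but RNA alone does not measure copies. Fewer copies in the ATCC stock, or regulation of the whole chromosome, would give the same values and were not tested.

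TKTL1, FLNA and EMD lie next to each other on chromosome X (154295671 to 154381523) and were lower in ATCC, TKTL1 at 44.4 ± 4.01 CPM against 457 ± 11.04 in DSMZ (n = 3 each) and EMD with 0 counts in ATCC. The neighbours IRAK1 (-0.95), DNASE1L1 (-1.80) and TAZ (-1.10) were higher in ATCC and RPL10 (-0.20) did not pass. In ATCC 11.1% ± 1.63 of FLNA counts lay in long transcripts reaching position 154370222 or beyond, against 95.3% ± 0.524 in DSMZ. These transcripts extend from the gene's 3' end over most of its length, so the share does not place reads in the 5' part. Not all of these reach the gene's 5' end at 154374638: ENST00000369856.7, with 14530 counts in DSMZ, reaches 154371222. The share of long transcripts does not decide whether DNA is lost or rearranged at this place in the ATCC stock. It restates transcript shares that were already seen. ENST00000610817.4, annotated from the 5' end of FLNA, had 236 estimated counts in ATCC, which do not show where along it the reads lie. For TKTL1 the full-length ENST00000369915.7 had 1930 counts in ATCC, while the short ENST00000426989.5 had 1722 there and 0 in DSMZ. A loss or rearrangement of DNA thus stays open. Silencing of the promoters, a start of transcription inside FLNA, and the cause of the low TKTL1 and EMD values were not tested.

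ATCC replicate 2 lay farther from ATCC replicates 1 and 3 than these lay from each other, with a distance ratio of 1.68. GC content took up 50.7% of the variance of its deviation, and the bound for the next test was set with that share known: removing the GC trend from each ATCC library lowered the ratio to 1.25, while removing the length trend left 1.59. In this library, 15 genes seen in DSMZ and not in ATCC replicates 1 and 3 reached 0.515% of their DSMZ level. This argues against RNA of DSMZ cells mixed in beyond about that share. Replicates 1 and 3, at 0.391 and 0.292%, were held low by the choice of these genes and are no reference. The values are consistent with a GC-dependent step of library preparation or sequencing in this library, but about as much of its variance is not taken up by GC content. No biological explanation was tested, and the labels name no batch.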
